A study of Mus musculus with 4 samples.

How the data were processed

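Per the labels' protocols, total RNA was extracted from mouse liver with RNAiso, and libraries were made with a NEBNext Ultra kit and sequenced on an Illumina HiSeq instrument. The 4 libraries came from 8-week-old C57BL/6J mice, 2 labelled wild type (WT) and 2 labelled Ern1-LKO, a label that stands for a liver-specific knockout of Ern1. Whether the libraries keep strand, and whether reads were counted by strand, is not given in the sources used here, so a gene and its antisense partner could not be told apart.

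Per the submitters' processing notes, bcl2fastq, FastQC 0.11.3, TopHat2 2.0.14 and Cufflinks 2.2.1 were used with the mm10 build; the notes give them no roles. The gene annotation, the scaling between libraries and the dispersion method are not given in the sources used here. Per the file headers, the authors' deposited table has the columns of a Cuffdiff comparison, with 1 FPKM value (fragments scaled by transcript length and by mapped fragments) per genotype and locus. Per the file headers, the same table gives the authors' log2 fold change of LKO over WT, their test statistic (a signed score), their p-value and their q-value. The log2 fold changes equal the log2 of the ratio of the 2 FPKM values to within 1.3e-05, and Benjamini-Hochberg adjustment of the deposited p-values over loci of status OK gave the same 365 calls as the deposited q-values.

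The table held 25572 loci, and 1 further line held no values and was not used here. The authors tested 13320 loci (status OK); 12238 were too low to test, 13 had too many fragments to estimate, and 1 failed. A value of 0 at loci of the third kind, Alb among them, is a failed estimate and was not used. Loci without a gene name numbered 1652, and they held 43.1% of the summed FPKM in WT and 42.6% in LKO-labelled libraries; 4 of them alone held 39.6% and 39.7%. A further 449 loci list several genes, which the table does not separate, and these are named as combined loci. The table's starts lie 1 below those of GENCODE M21 for 6477 matched symbols, against 627 that were equal, so 1 was added and coordinates are given 1-based on mm10. Of 23137 single-gene symbols, 22191 matched GENCODE M21, 99.7% of them on the same chromosome.

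Because the FPKM columns carry a value per genotype and not per library, no test across animals was run here. The plan fixed before the data were examined named this case: a gene is called when the authors' q lies under 0.05, with no test of another kind. FPKM values keep no read depth, so the depth per library is unknown and no counting interval or detection limit was computed. A standard error (SE) of each log2 fold change was derived as the absolute log2 fold change times the natural log of 2 over the absolute test statistic. The z it gives, over the z of the deposited p, had a median ratio of 1.02 over 6239 loci (5th to 95th percentile 0.997 to 1.09), though it fails at a few loci of low FPKM.

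Gene lists numbered 43, with 1053 memberships of 997 distinct genes, and were fixed before the data were examined. They cover the unfolded protein response, liver metabolism, stress and inflammation, and cell types that liver tissue could hold. For each list, the members called higher and lower were counted, and members with an adjusted p under 0.05 were counted again with p-values adjusted over the list alone. Calls were compared with all other tested single-gene loci by one-sided Fisher's exact tests in each direction, with Benjamini-Hochberg adjustment over the 86 tests. The median change on the log2(FPKM + 1) scale was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins, again with adjustment over the 43 lists. A pseudocount of 1 understates the change of low genes. Genes are not independent replicates, so these tests describe the 2 pooled profiles and not the variation between mice.

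The genes named were chosen by a rule fixed before the data were examined. It took Ern1, then the 10 higher and 10 lower called genes with the largest change on the log2(FPKM + 1) scale and an FPKM of at least 1 in the higher genotype, leaving out predicted genes and small RNAs. It added from each list up to 2 called members per direction, or the 2 of highest mean FPKM where none was called, and the 5 called genes of highest mean FPKM. Other genes are named where they complete a count of called genes or as further examples, and were chosen after their values were seen.

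Alternatives were a pseudocount of 0.1 or 0.5, filters at an FPKM of 1 or 5, a q threshold of 0.01, a 2-fold minimum, adjustment over expressed loci alone, and log2 fold changes shifted so that their median over expressed loci is 0, with p-values from a normal approximation that was also run without the shift. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The call and list steps were tested on simulated data for 10144 genes of this comparison, 200 of them changed. The calls took in 97.5% of genes at a log2 fold change of -1.5, 87.5% at -1.0, 82.5% at 1.0, 22.5% at -0.6 and 32.5% at 0.6, and 6.52% of calls were unchanged genes. None of 40 simulated lists of unchanged genes passed either list test. The simulated noise was independent between genes and had the implied SE that also gave the p-values. The simulation therefore checks the steps, and not how the tests behave with correlated genes or with the spread between mice.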

Results

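Liver transcripts were profiled by RNA sequencing in 8-week-old WT mice and in mice labelled Ern1-LKO, with 2 libraries per genotype. Ern1 encodes IRE1α, the endoplasmic reticulum (ER) stress sensor whose RNase splices Xbp1 mRNA, and the comparison asks which liver transcripts differ between WT mice and those labelled as its liver-specific knockout. Expression is given as the authors' FPKM, 1 value per genotype, so the spread between mice of a genotype is not shown and either animal of a pair could carry a difference. Error is given as the SE implied by the authors' test statistic, and the read depth is unknown.

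The authors called 365 of 13320 tested loci at q under 0.05, of which 211 were higher and 154 lower in the LKO-labelled libraries. XBP1 targets of the ER secretory pathway fell at 26 of 59 tested genes, lipid synthesis genes at 6 of 30 and PPARα and fatty acid oxidation genes at 4 of 38, while 11 of 25 matrix genes, 6 of 26 immediate early and heat shock genes and 4 of 32 PERK-ATF4 targets rose. The calls made up 2.74% of tested loci, against 1368 loci at an unadjusted p under 0.05. At least a 2-fold change was seen at 165 called loci, 107 higher and 58 lower. Among 10926 expressed loci the median log2 fold change was -0.02 with an SD of 0.37, and the median implied SE was 0.19. Calls at 53 loci had an FPKM under 1 in both genotypes, and 14 had a value of 0 in a genotype. The medians of 25 of the 43 gene lists lay outside matched random lists (adjusted p under 0.05 by percentile among random lists). Such a median is therefore common here and does not by itself set a list apart.

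**Figure D1:**
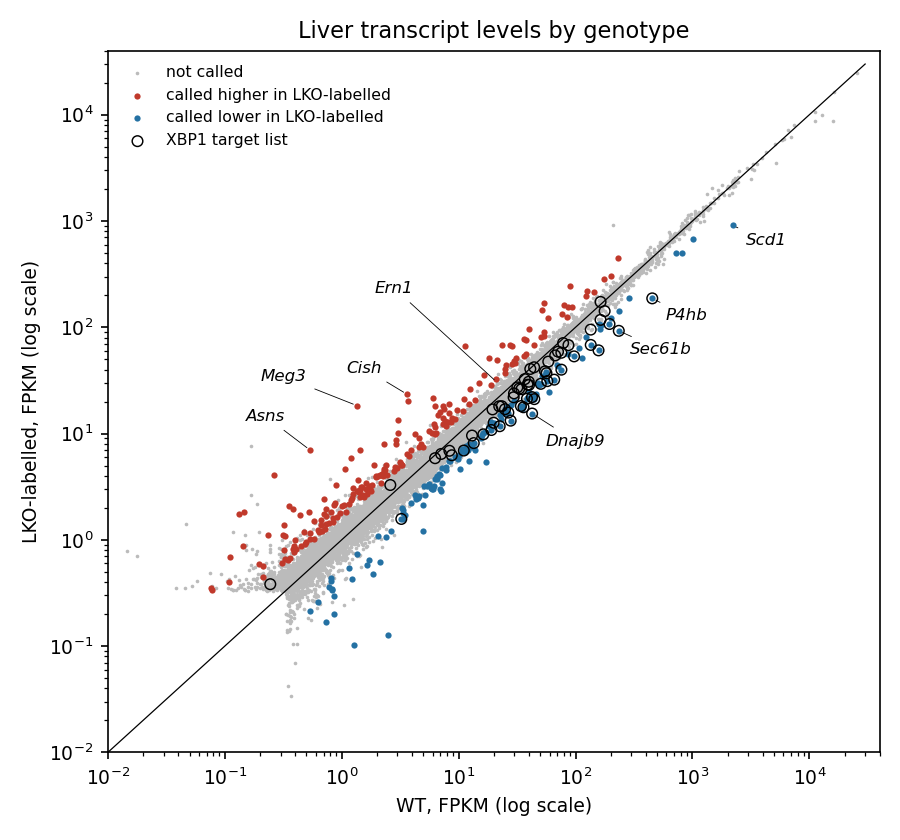
Authors' FPKM per locus in WT (x axis, log scale) and LKO-labelled libraries (y axis, log scale), for tested named loci above 0.01 in both. Red and blue points are loci called higher or lower, circles are the XBP1 target list, and the line marks equal values; 56 of the 59 circles lie below it.

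Ern1 itself, at chromosome 11, 106390552 to 106487865, was not lower in the LKO-labelled libraries. Its FPKM was 21.4 in WT and 30.2 in LKO-labelled libraries, a ratio of 1.41, and the authors' deposited table gives a log2 fold change of 0.50 (implied SE 0.19), p = 0.0084 and q = 0.172. A gene-level FPKM also counts exons outside a deleted part, so this value does not check the genotype labels, and directions below are those of the libraries labelled Ern1-LKO.

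Targets of XBP1, the transcription factor made from the Xbp1 mRNA that IRE1α splices, were lower. Of 59 tested members, 26 fell and none rose, and 56 lay below WT. The enrichment of falls had an adjusted p of 3.7e-33 by Fisher's exact test, 40 members fell with p-values adjusted over the list alone, and the list's median change of -0.48 on the log2(FPKM + 1) scale lay below all 10000 matched random lists. Dnajb9, a co-chaperone of the ER, fell from 42.5 to 15.4 FPKM, and the translocon subunits Sec61g and Sec61b fell from 157 to 60.7 and from 235 to 92.6. In the authors' deposited table the log2 fold changes of these genes are -1.46 (implied SE 0.17), -1.37 (0.17) and -1.34 (0.17), each at the table's smallest q of 0.00343. P4hb, the protein disulfide isomerase, fell from 453 to 187 FPKM, and the ER signal peptidase subunit Sec11c from 35.9 to 17.7. Xbp1 itself was at 77.3 FPKM in WT and 79.2 in LKO-labelled libraries, with q = 0.999 in the authors' deposited table; total Xbp1 does not measure splicing.

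Targets of the other arms of the unfolded protein response changed in part. Of 12 tested ATF6 targets, 4 fell, with an adjusted p of 0.00014 by Fisher's exact test: Sdf2l1 (44.4 to 21.1 FPKM), Creld2 (27.9 to 13.2), Dnajc3 and Hyou1. Sdf2l1, Creld2 and Dnajc3 are also on the XBP1 list, and without shared members 1 of 9 fell, Hyou1. Of 32 targets of PERK and ATF4, 4 rose and 2 fell, with an adjusted p of 0.0136 for rises by Fisher's exact test. Asns, which makes asparagine, rose from 0.54 to 6.97 FPKM, a ratio of 12.9, and the authors' deposited table gives a log2 fold change of 3.69 (implied SE 0.32). Chac1 rose from 2.31 to 7.98 FPKM, and Psat1 and Ddit4 also rose. Eif2ak3, which encodes PERK, fell from 4.58 to 2.61 FPKM, and Atf5 fell from 159 to 107. The list as a whole had a median log2 fold change of -0.03, so the rises were confined to part of it. Among 23 substrates of IRE1-dependent RNA decay, Col6a1 (1.72 to 3.20 FPKM) and Ces1g (84.2 to 124) rose and none fell, which did not pass Fisher's exact test (adjusted p = 0.21), while the list's median lay above all matched random lists. Col6a1 is a collagen, and collagens rose with the matrix genes described below.

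**Figure D2:**
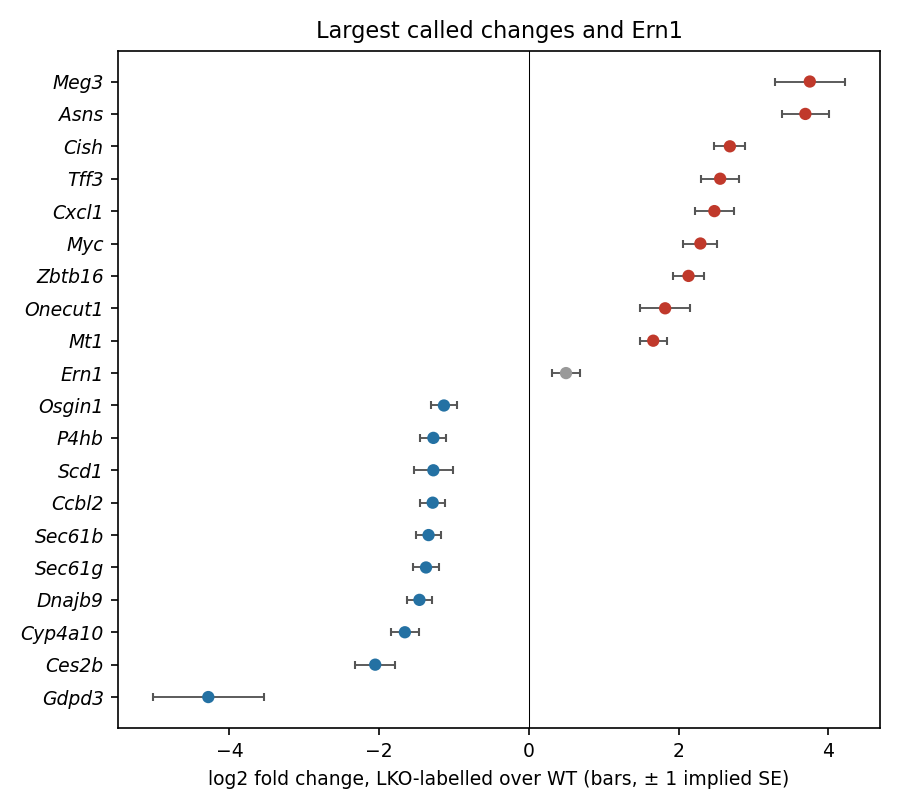
Log2 fold change of LKO-labelled over WT in the authors' table (x axis) for the called loci of largest rise other than Rian, whose implied SE of 4.25 exceeds the axis, the 10 of largest fall, and Ern1. Bars are ±1 SE implied by the authors' test statistic; red, blue and grey points are called higher, called lower and not called.

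Lipid metabolism genes fell in part. Of 30 lipid synthesis genes, 6 fell and 2 rose (adjusted p = 2.9e-05 for falls by Fisher's exact test). Scd1, the main liver desaturase, fell from 2203 to 910 FPKM, and the authors' deposited table gives a log2 fold change of -1.28 (implied SE 0.26). Elovl5 fell from 162 to 96.1 FPKM, and Elovl3, Acacb, Plin2 and Pnpla3 also fell. Lpin1, a phosphatidate phosphatase, rose from 51.3 to 146 FPKM and Lpin2 from 53.9 to 82.3. Of 38 PPARα and fatty acid oxidation genes, 4 fell and 1 rose (adjusted p = 0.0121 for falls by Fisher's exact test). Cyp4a10 fell from 17.1 to 5.42 FPKM, Cyp4a31 from 1.87 to 0.48, and Vnn1 and Crat fell, while Ppargc1a rose from 1.39 to 2.91. The paralogs Cyp4a10 and Cyp4a31 share sequence, so their falls may not be separate. With members of mean FPKM at or above 5, 2 of 30 fell, which did not pass Fisher's exact test (adjusted p = 0.261). None of 27 cholesterol synthesis genes was called, Sc5d standing at 283 and 270 FPKM and Fdps at 149 and 194, although 7 had an unadjusted p under 0.05 and 19 lay above WT (median change 0.06 on the log2(FPKM + 1) scale, percentile 98.9 among matched random lists).

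Genes of glucose metabolism, bile acids and drug metabolism showed few calls. Got1 (86.6 to 154 FPKM), Ppargc1a and Ppp1r3g rose among 26 glucose genes (adjusted p = 0.0424 by Fisher's exact test). Of the 26 glucose genes 19 lay above WT, and 6 rose with p-values adjusted over the list alone. The glucose list's median change of 0.20 on the log2(FPKM + 1) scale lay above all matched random lists. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 11.1 to 21.1 FPKM, whereas Nr0b2, which encodes the repressor SHP, fell from 39.9 to 24.5 and Slco1a4 from 8.39 to 5.58; 24 other bile acid genes were not called. Por (76.2 to 133 FPKM) and Cyp2a5 (201 to 306) rose among 37 P450 and drug metabolism genes. Alas1, the first enzyme of heme synthesis, rose from 89.2 to 244 FPKM among 17 iron and heme genes. Of these 17, 7 lay above WT and 10 below, and with p-values adjusted over the list alone 1 rose and 3 fell. None of the last 3 lists passed Fisher's exact test in either direction, nor did the 21 lipoprotein assembly genes, of which P4hb alone fell. On the log2(FPKM + 1) scale the median changes of the drug metabolism list (0.08) and the lipoprotein list (-0.08) were small, at percentiles 99.9 and 0.98 of matched random lists.

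Sex-biased and growth hormone genes changed in both directions. Of 9 tested female-biased genes 3 rose, Cyp2c40 (5.54 to 10.6 FPKM), Cyp2c69 (to 3.41, a ratio of 2.13) and Fmo2 (adjusted p = 0.00382 by Fisher's exact test). Of 24 male-biased genes 3 rose, among them Susd4 (6.66 to 15.1 FPKM) and Scara5 (2.37 to 5.11), and 3 fell, among them Cyp2u1 (35.9 to 18.0) and Elovl3 (164 to 105); by Fisher's exact test the adjusted p was 0.036 for rises and 0.0212 for falls. Paralogs of the Cyp2c and Cyp4a families share sequence, and their values are uncertain. Cish, which restrains cytokine and growth hormone signalling, rose from 3.64 to 23.4 FPKM, and Socs2 from 4.56 to 7.52, while Bcl6 fell from 13.9 to 6.98 and Stat5a from 5.38 to 3.20; the growth hormone list of 14 did not pass Fisher's exact test (adjusted p = 0.0966 for rises and 0.0615 for falls), but passed for rises after centring (0.0193) and for falls at q under 0.01 (0.0306). The 4 Y-linked genes were not called, Eif2s3y standing at 32.4 and 32.7 FPKM and Ddx3y at 15.6 and 14.7.

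Immediate early, inflammatory and acute phase genes rose in part. Of 26 immediate early and heat shock genes, 6 rose, Myc (1.44 to 7.03 FPKM), Fos (1.89 to 5.02), Egr1, Junb, Zfp36 and Gadd45g, and Bag3 fell from 18.2 to 11.7 (adjusted p = 4.6e-05 for rises by Fisher's exact test). None of the 6 is a heat shock gene, and Nr4a1, an immediate early gene outside the list, was called lower. Cxcl1, a neutrophil chemokine, rose from 3.66 to 20.4 FPKM, and Tnfaip3 and Vcam1 also rose among 22 inflammation genes (adjusted p = 0.03 by Fisher's exact test). Among the cell type markers given below, 16 of 16 Kupffer and 8 of 11 lymphocyte genes lay above WT, and 4 of 5 neutrophil genes below. Among 35 acute phase genes 4 rose and 1 fell (adjusted p = 0.0173 for rises by Fisher's exact test), and 7 rose and 4 fell with p-values adjusted over the list alone. The metallothioneins Mt1 and Mt2 rose from 54.0 to 171 and from 18.3 to 51.5 FPKM, with Socs3 and Steap4, while Orm1 fell from 1002 to 684. Ciart (3.02 to 10.1 FPKM), Usp2 (4.22 to 9.90) and Per3 rose among 21 clock genes (adjusted p = 0.0283 by Fisher's exact test). None of 35 interferon genes was called, nor of 12 antigen presentation genes; Bst2 stood at 313 and 251 FPKM, Ifi27 at 145 and 122, B2m at 2165 and 1818, and H2-K1 at 839 and 756. The antigen presentation list as a whole ran the other way from B2m and H2-K1: 8 of 12 genes lay above WT, its median change of 0.21 on the log2(FPKM + 1) scale lay above all matched random lists, and 3 rose with p-values adjusted over the list alone.

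Matrix genes rose. Of 25 tested fibrosis and matrix genes, 11 rose and none fell, and 24 lay above WT (adjusted p = 2.0e-12 by Fisher's exact test; 13 rose with p-values adjusted over the list alone). Acta2, the smooth muscle actin, rose from 1.21 to 5.86 FPKM, and the authors' deposited table gives a log2 fold change of 2.28 (implied SE 0.23). Col1a1 rose from 1.38 to 3.66 FPKM and Col3a1 from 4.62 to 9.18. Adipocyte genes, given with the cell type markers, also lay above WT. Matrix genes are low in liver: with members of mean FPKM at or above 5, 2 rises were counted and the list no longer passed Fisher's exact test. Of the 35 lists that keep at least 3 members with that filter, Fisher's exact test was passed by the falls of XBP1 targets, ATF6 targets and lipid synthesis genes and by the rises of immediate early genes only.

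Markers of other cell types moved as follows. The stellate cell list had 3 rises among 15 genes, all collagens on the matrix list (adjusted p = 0.0136 by Fisher's exact test), and 0 of 12 without the members it shares with that list. Of the 15 genes, 14 lay above WT and 7 rose with p-values adjusted over the list alone. The stellate list's median change of 0.26 on the log2(FPKM + 1) scale was at percentile 99.99 of matched random lists. The 17 hepatocyte genes had no call and a median log2 fold change of -0.00049, with Ttr at 7027 and 6212 FPKM and Trf at 6032 and 5928. Pericentral genes had 1 rise, Rhbg (6.97 to 16.0 FPKM), and 1 fall, Tbx3 (5.11 to 3.18); 10 of 12 lay above WT, and their median change of 0.28 on the log2(FPKM + 1) scale lay above all matched random lists. The 12 periportal genes had no call, with Ass1 at 2238 and 2458 and Pck1 at 1062 and 1247. Of 16 Kupffer cell genes none was called, although all 16 lay above WT with a median change of 0.26 on that scale, above all matched random lists, with Lyz2 at 41.4 and 49.6 FPKM and Slc40a1 at 44.2 and 46.0. Vwf rose from 0.85 to 1.46 FPKM among 16 endothelial genes, Cd4 from 0.74 to 1.40 among 11 lymphocyte genes, 8 of them above WT with a median log2 fold change of 0.45, and Onecut1 from 6.06 to 21.4 among 9 bile duct genes. Neutrophil genes were not called, S100a8 standing at 16.1 and 8.16 FPKM and S100a9 at 5.68 and 4.13, but 4 of 5 lay below WT and their median change of -0.37 on the log2(FPKM + 1) scale was at percentile 0.01 of matched random lists. None of 11 muscle genes was called, Acta1 standing at 18.0 and 20.5 FPKM and Tnnt3 at a ratio of 1.07, but all 11 lay above WT, as did 24 of 25 matrix genes, with a median change of 0.13 on that scale (percentile 99.2). Hbb-b2 rose from 27.4 to 68.7 FPKM, and the combined locus Hbb-b1 and Hbb-bs from 232 to 444, in loci that share near-identical sequence. Of 6 tested adipocyte genes 1 was called, Retn, listed at 0 in WT and at 2.06 FPKM in LKO-labelled libraries, and 5 lay above WT. Adipoq was at 0.05 and 1.42 FPKM and Cfd at 0.17 and 7.66, neither called, and the adipocyte list's median change of 0.96 on the log2(FPKM + 1) scale lay above all matched random lists (adjusted p = 0.00066, by percentile among random lists, a permutation over genes), although Fisher's exact test was not passed (adjusted p = 0.329). Of 11 tested pancreatic acinar genes 6 were called lower (adjusted p = 3.7e-08 by Fisher's exact test), each below 1 FPKM in WT and listed at 0 in LKO-labelled libraries, Try4 at 0.74 and Pnlip at 0.60 among them. Ctrb1 (1.41 FPKM in WT) and Clps (1.12), also listed at 0 in LKO-labelled libraries, were not called (p = 0.0936 and 0.112 in the authors' deposited table). Calls at a value of 0 thus did not follow the WT level, and the Fisher p rests on such calls.

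**Figure D3:**
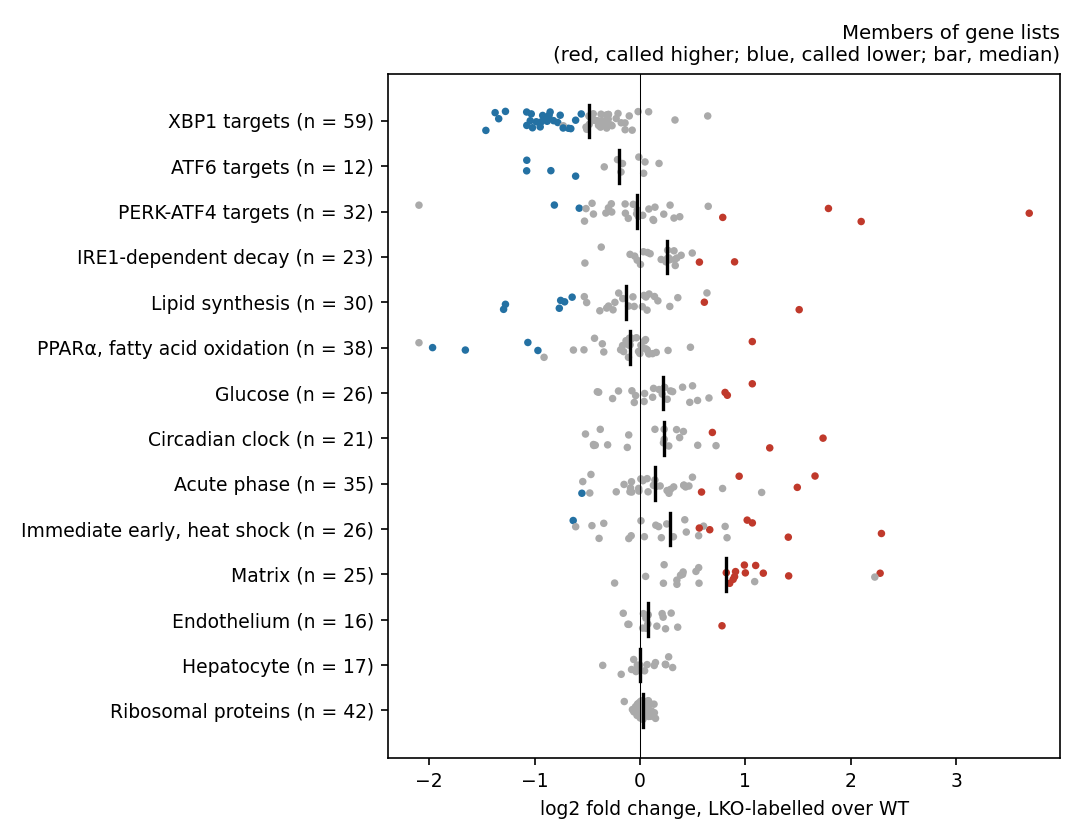
Log2 fold change of LKO-labelled over WT (x axis) for the tested members of 14 gene lists with a finite fold change. Each point is a gene, red called higher, blue called lower and grey not called, and bars are list medians; the XBP1 list has a median of -0.48 and the matrix list 0.82.

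The remaining lists held no calls, and their medians lay between the 13.1 and 78.9 percentiles of matched random lists. The 42 ribosomal protein genes of the list had a median log2 fold change of 0.03, with Rps27 at 2469 and 2606 FPKM and Rpl38 at 2442 and 2346. Rpl10 and Rpl36al, outside the list, fell from 813 to 497 and from 731 to 503 FPKM. None was called among 33 oxidative phosphorylation genes (Cox6a1 1313 and 1377, Ndufa4 1220 and 1236 FPKM), 29 proteasome genes (Psmb7 210 and 204, Psmb4 197 and 197), 21 autophagy and lysosome genes (Lamp2 301 and 288, Gabarapl1 279 and 281), 32 coagulation and complement genes (Fgg 2352 and 2398, Fgb 2125 and 2136), 15 NRF2 targets (Sod1 1649 and 1644, Gstm1 1220 and 1162) or 15 proliferation genes (Pcna 21.4 and 22.6, Ccnd1 10.5 and 6.44).

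Outside these lists the largest rises were at the combined locus of Meg3 (1.36 to 18.3 FPKM), an imprinted long noncoding RNA, at Tff3 (11.3 to 66.7), a secreted trefoil peptide, and at Zbtb16 (3.05 to 13.4). The combined locus of Rian, near Meg3 on chromosome 12, rose from 0.26 to 4.08 FPKM, with p = 0.0009 and q = 0.0364 in the authors' deposited table. Its implied SE of 4.25 does not match that p, so the derived SE fails at this locus and gives no error for the size. The largest falls outside the lists were at Gdpd3 (2.49 to 0.13 FPKM), Ces2b (4.99 to 1.20), Ccbl2 (59.9 to 24.6) and Osgin1 (113 to 51.5).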

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

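The named-loci, above-0, uncentred normal, combined-locus, no-contractile and no-pseudocount settings were chosen after seeing the data. No paired analysis was possible because the columns carry 1 value per genotype, and for the same reason the replicate block, leave-one-out, limma with or without trend, limma against the authors' test, and an estimated correlation were not run. The 365 calls (211 higher, 154 lower) became 197 with an FPKM of at least 5 (94 higher), 221 at q under 0.01 (124 higher, 97 lower) and 165 with a 2-fold minimum (107 higher, 58 lower); these settings take subsets of the calls. Called genes changed 2-fold on the log2(FPKM + 1) scale numbered 64, and 142 with a pseudocount of 0.1. Fisher's exact test passed for 16 lists and directions, and for 4 with members of mean FPKM at or above 5, where fewer genes were tested. The cause beyond that was not tested. Lists with a median outside matched random lists numbered 25, and 19 with the filter at 5. Their number stayed at 25 with the filter at 1, with a pseudocount of 0.1 and with combined loci. Pancreatic genes were too few to test with a filter at 1 or 5, and female-biased genes at 5. At q under 0.01, clock, glucose and lower male-biased genes no longer passed and lower growth hormone genes did, and erythroid genes passed with combined loci. The normal approximation alone ended the call of higher male-biased genes and added higher adipocyte and lower ATF4 genes; with centring as well, inflammation no longer passed and higher growth hormone genes did. Matrix rises went from 11 of 25 to 2 of 10 with the filter at 5, to 7 of 25 at q under 0.01 and to 10 of 23 without contractile genes. XBP1 target falls stayed between 23 and 27 under all settings run. The normal approximation gave 481 calls (283 higher, 198 lower), and with centring 474 (301 higher, 173 lower). Ern1 ranged from 0.48 to 0.50 on the log2 scale. Over 135 other results and their settings, 473 values were classed as unchanged and 26 counts moved by over 1.5 times. The Rian locus lost its call with the normal approximation, centred or not, which uses the derived SE that fails at this locus. Counts were classed by size, but genes only by their call and, where called, their direction. A pseudocount cannot reverse a direction, so the 101 unchanged values at a pseudocount of 0.1 were fixed in advance and show nothing.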

Other observations

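All tests of this part except the length and GC regression were chosen after the result was seen. A scan of 379 gene symbol stems with at least 5 tested members, 758 tests in all, found 3 past an adjusted p of 0.05 by Fisher's exact test. Collagen genes rose at 9 of 20 (adjusted exact p = 5.9e-09), with Col4a3, Col4a5, Col5a2 and Col6a3 added to those on the matrix list. Sec genes fell at 6 of 25 (adjusted exact p = 0.00016), all on the XBP1 list. Cytochrome P450 genes rose at 7 of 65 (adjusted exact p = 0.0187), among them Cyp2g1 and Cyp4f16, and fell at 4, Cyp2u1, Cyp3a59, Cyp4a10 and Cyp4a31 (adjusted exact p = 0.639), with a median log2 fold change of 0.03 over all 65.

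The fall of XBP1 targets was weighed against 3 technical explanations. Library scaling would move ribosomal protein genes alike, and their median log2 fold change was 0.0262. A loss of hepatocytes would lower the hepatocyte list, whose median was -0.00049. After regression on transcript length, GC content and expression level in 20 bins each over 9783 genes, the median residual of 58 members was -0.47 (interquartile range -0.87 to -0.25). Reduced XBP1 activity in the libraries labelled Ern1-LKO is a candidate explanation that stays open as a hypothesis; spliced Xbp1 reads or XBP1 protein would test it and were not analysed here.

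The rise of matrix genes was weighed against changes in tissue makeup. A lower share of hepatocytes would raise other cell types alike, but the matrix median exceeded the endothelial median by 0.74 (permutation p = 4.0e-05, 25 and 16 genes). Median log2 fold changes of Kupffer (0.27, 16 of 16 above WT), lymphocyte (0.45) and muscle genes (0.19, 11 of 11) were also above 0, so a lower hepatocyte share may still add to the rise. The endothelial median (0.08, 13 of 16 above WT) was lower than these. Its comparison with the matrix list treats genes as independent. The matrix list was taken up because it rose, which can make both permutation p-values of this paragraph too small. At most, the comparison goes against an equal rise of all other cells. An unequal rise stays open. More stellate cells of unchanged state would raise their other markers, which had a median of 0.18 with 9 of 10 above WT, below the matrix list (permutation p = 0.00052). None of these markers was called, but their median on the log2(FPKM + 1) scale, 0.15, was at percentile 98.25 of matched random lists. More stellate cells may therefore add to the rise, and fibroblasts without these markers stay open. Contractile genes were above WT at 13 of 13 with a median log2 fold change of 1.09 and 4 called, Acta2, Myh11, Actg2 and Myl9, and a stretch of muscular vessel or duct wall in 1 sample cannot be told apart from a change in both mice. Nor can adipose tissue in 1 LKO-labelled sample: the adipocyte list had a median of 0.96 on the log2(FPKM + 1) scale, with Cfd at 0.17 and 7.66 FPKM. A response to the genotype may also contribute and was not tested.

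Clock and hormone-responsive genes were weighed against the hour of harvest and glucocorticoid exposure. Evening clock genes had a mean log2 fold change 0.99 above that of morning clock genes, with 11 of 12 above WT and 4 of 4 below. That split of the clock list was made after its calls had been seen, with the 3 called genes in the evening set and 5 tested members in neither, of which 3 lay below WT, among them Bhlhe40 (log2 fold change -0.38 in the authors' deposited table). The test is therefore void, although it was first read as favouring a difference in the hour of harvest, which cannot be told apart from an effect of the genotype on the clock. A list of 17 glucocorticoid-responsive genes had a median of 0.31 on the log2(FPKM + 1) scale, above the matched random lists and past the bound set for it, with 14 above WT. That list was drawn up after called genes had been seen and holds 6 of them, so the test is void and was first read as favouring the explanation. The 6 are Fkbp5, Zbtb16, Mt1, Mt2, Lpin1 and Ddit4. Mt1 and Mt2 are also counted above as acute phase rises, Lpin1 as a lipid synthesis rise and Ddit4 as a PERK-ATF4 rise. Tsc22d3, Sgk1 and G6pc lay below WT, and the explanation cannot be told apart from others.

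Within 8 Mb of Ern1, 1 of 168 tested loci was called (0.595%), against 2.77% elsewhere (Fisher's exact test, one-sided p = 0.991), which argues against an excess of changes around the targeted locus. Of 23 pancreatic acinar genes, 19 were above 0 in WT and 3 in LKO-labelled libraries. Acinar tissue in a WT sample was tested on the 3 acinar genes of highest WT value, and 1 of them was at most 0.1 of its WT value in LKO-labelled libraries, short of the bound set for that explanation, which was first read as arguing against it. Cela1 (46.4 and 58.5 FPKM) and Cela2a (2.95 and 1.78) missed the bound, but each remains at a level that would hide a small share of acinar cells, and neither difference is resolved (p = 0.0575 and 0.332 in the authors' deposited table). Of the 19 genes, 16 were listed at 0 in LKO-labelled libraries, among them Ctrb1 (1.41 FPKM in WT) and Clps (1.12), while Ctrl was at 0.63 and 0.50. With values this low, acinar cells in a WT sample cannot be told apart from a difference between the genotypes.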
